A study of Mus musculus with 12 samples.

How the data were processed

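RNA of mouse blood cells was measured on 12 one-colour Affymetrix mouse arrays. Per the labels, the cells came from mice with or without the Stat5a and Stat5b genes and were treated with or without CMP. The labels do not say what CMP is, which blood cells were used, or whether the arrays of a group come from separate animals or cultures. The p-values therefore measure only the spread between these samples. The titles of naming sets A and C carry the letters CMP on every array, with a plus or minus sign, while the treatment protocols name CMP as what was given. CMP may therefore name what was given or the cells themselves, with the sign standing for something the labels do not state, and the data do not settle this. Arrays were grouped by their titles, and the group names take the protocols' wording for CMP. The CMP effect means only the difference between arrays labelled with and without CMP.

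The deposited values are linear intensity signals per probe set, made by the authors with MAS5, as the labels name the tool. The labels give no version, scaling target or detection calls. The 1 deposited table held 45101 probe sets, all with values above 0. In each array the mean after trimming 2% at each end was 500, the value to which the authors scaled the arrays. The array medians differed by at most 0.67 on the log2 scale, less than the limit of 1 set before the data were examined, so the deposited scaling was kept. An array has no counting depth, and the number of arrays limits the precision.

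The supplied probe table paired 34958 probe sets with 1 gene symbol and 932 with several, and 9211 probe sets were not listed. Of these pairings, 34754 matched the annotation of assembly GRCm38.p6 by gene number. Values were taken as log2(signal + 32). Each gene was represented by its probe set with the highest mean, among those with 1 symbol. The table was used as deposited, and genes with a mean log2 value below 6.76, the median of all probe sets, were left out, which left 10583 genes.

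The titles come in 3 forms, called naming sets A, B and C, each with 1 array of each of the 4 groups. Residual differences between arrays followed these sets. Deviations from the group means correlated across genes at 0.41 to 0.77 in the 18 pairs of arrays within a set, and at -0.64 to 0.28 in the 36 pairs from different sets and groups. The set was therefore kept as a block, as chosen before the data were examined. In set B, the source label of the knockout array with CMP opens with another number than those of the other arrays.

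One fit over all 12 arrays (limma 3.58.1 in R 4.3.3, with eBayes and a trend in the variance prior) held the 4 groups and the naming set, with 6 residual degrees of freedom and 5.78 from the prior. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. Genes past it are called. The 5 contrasts were the CMP effect in controls and in knockouts, the knockout effect without and with CMP, and their interaction. Errors of log2 changes are standard errors of this fit, with 3 arrays per group.

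The treatment protocol of 1 array, the knockout without CMP of set B, calls it a control, while its title and its partner's labels make it a knockout. It was grouped by title, and the fit was repeated without it and with it as a control.

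Named genes were chosen by a rule. Stat5a and Stat5b were named in every contrast, with up to 10 called genes with the largest rise and 10 with the largest fall among those with the same sign in all naming sets. Where fewer than 5 genes of a direction were called, the 5 with the smallest p were named as not passing. Up to 4 members with the smallest p, called or not, were named per list. Members that moved against their list, and genes whose call appeared only in other settings, were named after their values were seen.

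A total of 28 gene lists of blood cell types, other tissues, Stat5 signalling and pathways were written from textbook knowledge before the data were examined. Lists with at least 5 tested members, 25 of them, were tested in the 5 contrasts, which gave 125 tests adjusted together. The eosinophil, hepatocyte and sex-linked lists had too few tested members (1, 1 and 4). The tests were limma's camera with a preset correlation of 0.01 and with an estimated correlation, and fry, which asks whether a list moves one way on balance and does not compare it with other genes. The median, the mean and the camera direction had the same sign in the 41 tests that passed with the preset correlation.

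The chain was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold among 10583. In the 4 contrasts of 2 groups it called 46 to 54 of the 2-fold and 98 or 99 of the 4-fold changes. In the interaction it called 12 and 86. Of the calls, 2.04% to 10.84% were genes that had not been changed.

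Alternatives chosen before the data were examined covered the scaling, the pseudocount, the level filter, the probe sets per gene, the variance prior, the naming set block, the groups in the fit, the array with conflicting labels, each left-out array and each left-out naming set. Array weights and the 3' to 5' signal ratios of beta-actin and Gapdh as covariates were added after the data were seen, as were the list tests without a naming set, with array weights and with the beta-actin covariate. No array was left out of the fit.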

Results

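The data were 12 arrays of mouse blood cells in 4 groups of 3: controls without CMP, controls with CMP, Stat5 knockouts without CMP and Stat5 knockouts with CMP. Each of the 3 naming sets, A, B and C, held 1 array per group. Array medians of the MAS5 signal ranged from 59.7 to 114, at the same trimmed mean in every array. On the main axis of variation between arrays, which held 38.5% of the variance, the 4 arrays of set B lay at 16.9 to 75.7 and the 8 others at -42.7 to 0.16. Within each set, the arrays with CMP also lay higher on this axis than those without. They lay at -1.13 and -4.96 against -42.5 and -42.6 in set A, and at 67.8 and 75.7 against 18.2 and 16.9 in set B. In set C they lay at 0.16 and -4.41 against -40.3 and -42.7. On the second axis (28.5%) the arrays with CMP lay lower in each set. Arrays of the same group correlated at 0.940 to 0.977 between sets A and C, and at 0.853 to 0.896 where 1 array was of set B.

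The knocked-out genes separated the genotypes in all 12 arrays. Stat5a and Stat5b, which encode transcription factors that carry cytokine signals, neighbour each other on chromosome 11 of GRCm38.p6, at 100859351 to 100885169 and 100780731 to 100859004. The brighter probe set of Stat5a gave signals of 660 to 1436 in the controls and 28.9 to 90.1 in the knockouts. That of Stat5b gave 1036 to 2177 and 7.28 to 82.8. Without CMP, Stat5a (-3.80 ± 0.29) and Stat5b (-4.59 ± 0.33) were lower on the log2 scale (SE, n = 3 arrays per group; limma adjusted p = 0.000107 for each), in 3 of 3 naming sets. The size of these differences depends on the constant added before the logarithm, as the knockout signals lay near the array medians or below. With a constant of 100 and of 1 it was -3.04 and -4.44 for Stat5a and -3.65 and -5.54 for Stat5b. The array whose protocol calls it a control had the low signals of a knockout in both genes. The other probe set of each gene was dimmer in the controls, at 38.1 to 157 for Stat5a and 87.7 to 203 for Stat5b, and lower in the knockouts, at 0.970 to 17.9 and 48.0 to 85.1. With CMP, Stat5a was at -0.32 ± 0.29 in the controls (adjusted p = 0.459) and -0.28 ± 0.29 in the knockouts (adjusted p = 0.538), and Stat5b at -0.41 and -0.19 (adjusted p = 0.404 and 0.73).

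**Figure D1:**
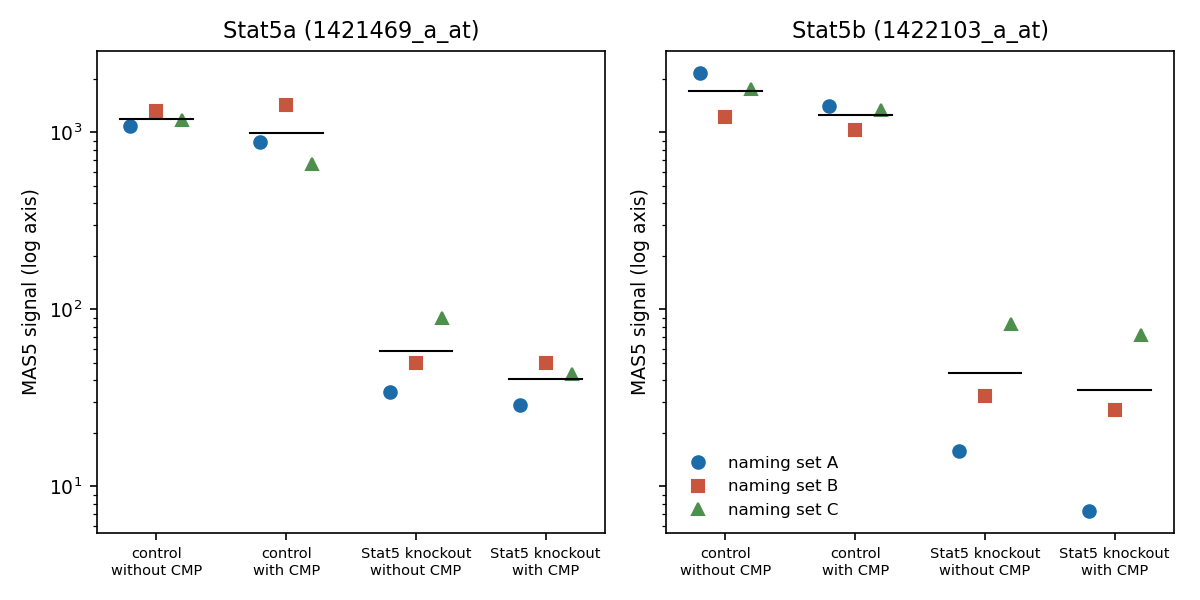
MAS5 signal of the brighter probe set of Stat5a and of Stat5b per array on a log axis, by group, with 1 point per array shaped by naming set and a line at the mean of the 3 arrays. All 6 knockout arrays lie at or below 90.1 and all 6 control arrays at or above 660.

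The CMP effect, the difference between arrays labelled with and without CMP, had the most genes called in the controls. Whether CMP names a treatment or the cells is not settled by the labels. Lpl, the lipoprotein lipase, rose by 5.22 ± 0.39 log2 units (SE, n = 3; adjusted p = 2.33e-05), and Trib3, a pseudokinase of the amino acid stress response, by 5.76 ± 0.49. Csf2rb2 and Csf2rb, beta chains of cytokine receptors, rose by 4.26 ± 0.33 and 2.81 ± 0.27. Fosb (-5.30), Jun (-3.88), Fos (-3.73) and Egr1 (-3.16), transcription factors of the immediate early response, fell. Each of these genes moved the same way in 3 of 3 naming sets. The rule for naming the largest changes required this, so that it is no separate support. Without CMP the mean of Trib3 was below the level filter, so that the size of its rise depends on the added constant (4.56 with 100 and 7.54 with 1).

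In all, 1119 genes rose and 1225 fell of 10583 tested (3849 at an unadjusted p under 0.05, with 529 expected by chance). More than 2-fold changes were seen in 663 of the genes that rose and 586 of those that fell. Others among the largest rises were Emp1, a membrane protein (5.37 ± 0.50), Pmepa1, an inhibitor of TGF-beta signalling (4.43), the large scaffold protein Ahnak (4.31) and its relative Ahnak2 (3.88). Acod1, which makes itaconate in activated macrophages (4.15 ± 0.88, adjusted p = 0.00681), Chac1, which breaks down glutathione (3.84), and the chemokine Ccl5 (3.73 ± 0.92, adjusted p = 0.0141) followed. The rise of Ccl5 was 6.50 in set A and 0.71 in set C. Among the falls were Atp1b2, a subunit of the sodium pump (-3.59), Car1, a carbonic anhydrase of red cells (-3.51), Dusp1, a phosphatase of MAP kinases (-3.37), Tgfbr3, a co-receptor of TGF-beta (-3.35), Ung, which removes uracil from DNA (-2.92), and the kinase Sik1 (-2.88). The sizes and ranks of Pmepa1, Ahnak2, Acod1, Chac1 and Sik1, each with a group mean below the level filter, also depend on the constant. With 100 and with 1 they were 3.52 and 5.25, 2.92 and 4.89, 3.16 and 5.55, 3.09 and 4.53, and -2.24 and -3.44.

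Amino acid response and unfolded protein genes stood higher with CMP, with 23 of 37 members up, 1 down and 13 not called. Adjusted over the list alone, 25 were up and 2 down. Slc7a11, the cystine transporter, rose by 3.41 ± 0.25 from a mean below the level filter (2.36 and 4.74 with a constant of 100 and 1), Asns, which makes asparagine, by 2.53 ± 0.20, and Chac1 and Trib3 as given above. Sdf2l1, a chaperone partner of the endoplasmic reticulum, was the member that fell (-1.65 ± 0.35, named after its value was seen). The list passed camera (adjusted p = 7.64e-09, and 0.0959 as adjusted p with an estimated correlation). Cholesterol synthesis genes rose in 13 of 20 members with none called lower, and 14 adjusted over the list alone. Msmo1 (2.71 ± 0.21), Cyp51 (2.56 ± 0.22), Fdft1 (2.27 ± 0.17) and Hmgcs1 (2.08 ± 0.20), enzymes of that route, led them (camera adjusted p = 3.25e-09, and adjusted p = 0.1 with an estimated correlation). Inflammatory and NF-kB genes were up in 11 of 25 (13 adjusted over the list alone), among them Cd83 (3.0, or 2.0 and 4.42 with a constant of 100 and 1), Icam1 (1.88), Traf1 (3.0) and Clec4e (2.17), with an adjusted p = 1.18e-06 that became adjusted p = 0.465 with an estimated correlation. Their median was 1.79 in set A and 0.71 in set C. Cell death genes were up in 8 of 18 and down in 1 (9 and 1 adjusted over the list alone). The pro-apoptotic genes Bmf (2.41), Bcl2l11 (2.24) and Pmaip1 (2.08) and the inhibitor Birc3 (1.29) rose, while Cycs fell (-0.62 ± 0.19, named after its value was seen). This list had an adjusted p = 0.00739, and adjusted p = 0.252 with an estimated correlation.

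Ribosome biogenesis and MYC target genes were lower with CMP, with 23 of 35 members down and 1 up (24 and 1 adjusted over the list alone). Polr1b, a subunit of RNA polymerase I (-1.79 ± 0.19), Nop16 (-1.59), Cad, of pyrimidine synthesis (-2.11), and Wdr12 (-1.49) fell, and Shmt2 was the member that rose (0.79 ± 0.15, named after its value was seen). The adjusted p was 3.25e-09, and adjusted p = 0.0959 with an estimated correlation. S phase and replication genes were down in 14 of 30 and up in none, and 23 were down adjusted over the list alone, with Tk1 (-1.90), Dut (-1.51), Mcm2 (-1.34) and Lig1 (-1.13) at the front (adjusted p = 2.42e-08, and adjusted p = 0.394 with an estimated correlation). Mitosis genes were down in 16 of 31 (19 adjusted over the list alone), with Nuf2 (-1.37), Plk1 (-1.21), Aurkb (-1.17) and Cdk1 (-1.06), an adjusted p = 1.76e-07, and adjusted p = 0.419 with an estimated correlation. Immediate early genes were down in 10 of 25 and up in 1, also adjusted over the list alone, and Fosl2 was the member that rose (1.40 ± 0.30, named after its value was seen). This list had an adjusted p = 0.0228, and adjusted p = 0.837 with an estimated correlation, and 0.0645 without set B and 0.065 with the beta-actin ratio as a covariate. Its median was 0.10 in set A, -0.81 in set B and -0.98 in set C. Erythroid genes were down in 6 of 17 and up in 1 (9 and 1 adjusted over the list alone). The blood group genes Rhd (-1.82) and Rhag (-1.12) and the erythroid transcription factor Klf1 (-2.02) fell, while Sptb rose (0.86 ± 0.27, or 0.59 and 0.40 with a constant of 100 and 1, named after its value was seen). The erythroid list had an adjusted p = 0.0232, and adjusted p = 0.823 with an estimated correlation, and 0.394 with the beta-actin ratio as a covariate.

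Arrays with CMP also had a higher 3' to 5' signal ratio of beta-actin in 6 of 6 pairs of the same set and genotype. The ratio is taken here as a sign of RNA quality, and other reasons for a higher ratio were not tested. The mean log2 difference was 0.94 ± 0.51 (SD, n = 6 pairs; exact sign-flip permutation test, two-sided, p = 0.03125, the smallest that 6 independent pairs can give). For Gapdh it was higher in 5 of 6 pairs, by 1.20 ± 0.92 (SD, n = 6; exact p = 0.0625). The test treats the 6 pairs as independent, but the arrays of a naming set are not. Both p-values are therefore likely too small, and no conclusion is drawn from them. With the beta-actin ratio as a covariate, chosen after seeing the data, 1519 genes were called in the controls, 1261 of them among the 2344. Without the naming set block 470 genes were called, without set A 1055, without set B 3074 and without set C 571. Left-out single arrays moved the count by over 1.5 times for the control without CMP of set B (1294) and of set C (1291) and for the control with CMP of set B (1494) and of set C (1505). With the arrays centred on their medians, 728 genes were higher and 1892 lower (27.8% higher, against 47.7%), and the median of all genes was -0.22 in place of -0.02.

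**Figure D2:**
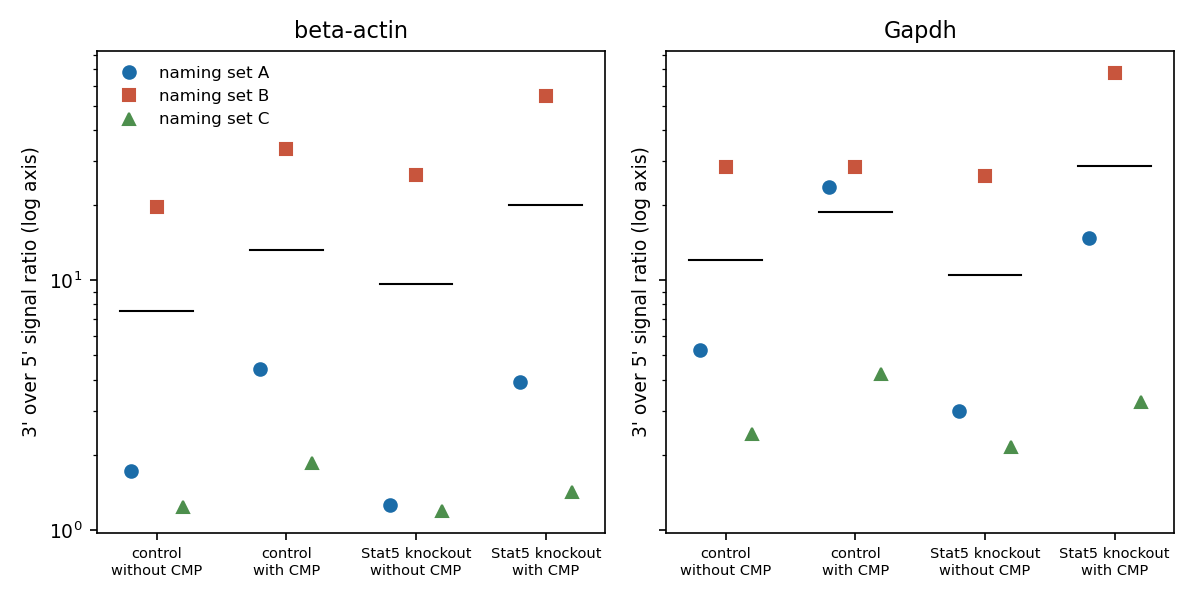
Signal ratio of the 3' to the 5' probe sets of beta-actin and Gapdh per array on a log axis, by group, with 1 point per array and a line at the mean of 3 arrays. The set B arrays lie at 19.7 to 54.8 for beta-actin, and the arrays of sets A and C at 1.19 to 4.40.

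Arrays labelled with and without CMP were also compared within the Stat5 knockouts. Lpl rose by 6.54 ± 0.39 (SE, n = 3; adjusted p = 5.27e-06), Emp1 by 5.00 ± 0.50, Trib3 by 4.56 ± 0.49 and Csf2rb2 by 3.75 ± 0.33. Fosb (-5.09 ± 0.39), Jun (-4.23), Car1 (-3.74), Tgfbr3 (-3.62) and Dusp1 (-3.54) fell. Each moved the same way in 3 of 3 naming sets, as the naming rule required.

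Here 956 genes rose and 1029 fell of 10583 (3590 at an unadjusted p under 0.05), with more than 2-fold changes in 541 and 534. The other largest rises were Slc7a11 (4.19 ± 0.25), Acod1 (4.12), Chac1 (4.07), Cd28, a costimulatory receptor best known from T cells (3.79 ± 0.29), Mir22hg, the host transcript of a microRNA (3.74), and Slc7a3, a transporter of cationic amino acids (3.62). The other largest falls were Apoe, an apolipoprotein (-3.17 ± 0.67), Fos (-3.11), Ermap, an erythroid membrane protein (-3.10 ± 0.64), Atp1b2 (-3.02) and Egr1 (-2.98). The change of Apoe was -1.80, -6.11 and -1.58 in sets A, B and C. Without CMP the means of Trib3, Slc7a11, Acod1, Chac1, Mir22hg and Slc7a3 were below the level filter, so that their sizes and ranks depend on the constant. With 100 and with 1 they were 3.67 and 5.61, 3.05 and 5.62, 2.99 and 5.72, 3.25 and 4.75, 3.01 and 4.40, and 2.78 and 4.37.

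Ribosome biogenesis and MYC target genes were down in 23 of 35 and up in 1 (25 and 1 adjusted over the list alone), with Polr1b (-2.17 ± 0.19), Cad (-2.02), Nolc1 (-1.76) and Nop16 (-1.65). Shmt2 rose (0.86 ± 0.15, named after its value was seen). The adjusted p was 1.33e-09, and adjusted p = 0.0959 with an estimated correlation. Amino acid response genes were up in 19 of 37 and down in 1, Sdf2l1 (-1.72 ± 0.35, named after its value was seen), or 21 and 3 adjusted over the list alone. Asns rose by 3.22 ± 0.20. Their adjusted p was 1.64e-07, and adjusted p = 0.0959 with an estimated correlation. Cholesterol synthesis genes were up in 10 of 20 and down in 1 (13 and 1 adjusted over the list alone), with Msmo1 (3.11), Fdft1 (2.18), Insig1 (1.93) and Hmgcs1 (1.89) up and Ebp down (-0.86 ± 0.26, named after its value was seen). Their adjusted p was 1.76e-07, and adjusted p = 0.15 with an estimated correlation. Inflammatory genes were up in 10 of 25 (12 adjusted over the list alone), with Clec4e (2.53), Cd83 (2.42, or 1.67 and 3.20 with a constant of 100 and 1), Clec4d (2.30) and Icam1 (1.77), an adjusted p = 3.57e-06, and adjusted p = 0.465 with an estimated correlation. Cell death genes were up in 7 of 18 (8 adjusted over the list alone), with Pmaip1 (2.49), Bmf (2.40), Birc3 (1.24) and Apaf1 (0.98), an adjusted p = 0.00437, and adjusted p = 0.226 with an estimated correlation.

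Immediate early genes were down in 8 of 25 (9 adjusted over the list alone), with Fosb, Dusp1, Egr1 and Jun as given above. The list had an adjusted p = 0.00383, and adjusted p = 0.833 with an estimated correlation, and 0.15 without set B and 0.0666 without the array of conflicting labels. Erythroid genes were down in 9 of 17 and up in 1 (11 and 2 adjusted over the list alone), with Car1, Ermap, Aqp1 (-2.57) and Klf1 (-2.43) down and Tfrc, the transferrin receptor, up (0.76 ± 0.18, named after its value was seen). The adjusted p of 0.00274 became adjusted p = 0.674 with an estimated correlation and 0.161 with the beta-actin ratio as a covariate. S phase genes were down in 7 of 30 (8 adjusted over the list alone), with Tk1 (-1.53), Lig1 (-0.86), Rrm1 (-0.82) and Uhrf1 (-0.76), an adjusted p = 0.00235, and adjusted p = 0.674 with an estimated correlation. Secondary granule and neutrophil genes had 1 member up, Ncf1 (0.82 ± 0.21), and 1 down, Camp (-1.47 ± 0.43), of 24, or 1 up and 0 down adjusted over the list alone. The list passed with an adjusted p = 0.0287, which became adjusted p = 0.859 with an estimated correlation and 0.0843 without set B, and 0.999, with the direction turned, with the beta-actin ratio as a covariate. Mitosis genes did not pass (adjusted p = 0.232, and adjusted p = 0.942 with an estimated correlation), but with the preset correlation passed downward without set B (3.41e-05), without the array of conflicting labels (0.0393), with array weights (0.000637) and with the beta-actin ratio as a covariate (0.00723), with Ube2c (-1.59), Ccnb2 (-1.02) and Aurkb (-0.77) down and Ndc80 up (1.07) of 31, or 2 down and 0 up adjusted over the list alone.

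The count of called genes in the knockouts fell to 650 with the beta-actin ratio as a covariate (566 of the 1985), to 298 without the naming set block, to 662 in a fit of these 6 arrays alone, and to 679 and 356 without sets A and C, while it was 2648 without set B. Without the knockout without CMP of set A, B or C it was 1298, 1000 or 937, where the set B array is the one with conflicting labels. With the arrays centred on their medians 37.5% of the called genes were higher, against 48.2%.

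The CMP effects of both genotypes were compared across the 10583 genes, which are not independent replicates. They correlated with a Pearson coefficient of 0.837 and a Spearman coefficient of 0.777, and the regression slope of the knockout effect on the control effect was 0.80. Within naming sets A, B and C the Pearson coefficient was 0.863, 0.481 and 0.884. Of the genes called in both genotypes, 701 were higher in both (101 for independent calls), 709 lower in both (119 for independent calls) and 0 opposite. The calls cannot be independent, since both contrasts share each gene's estimate of the spread and the arrays of a naming set share deviations. The numbers for independent calls are therefore no test of a shared response.

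**Figure D3:**
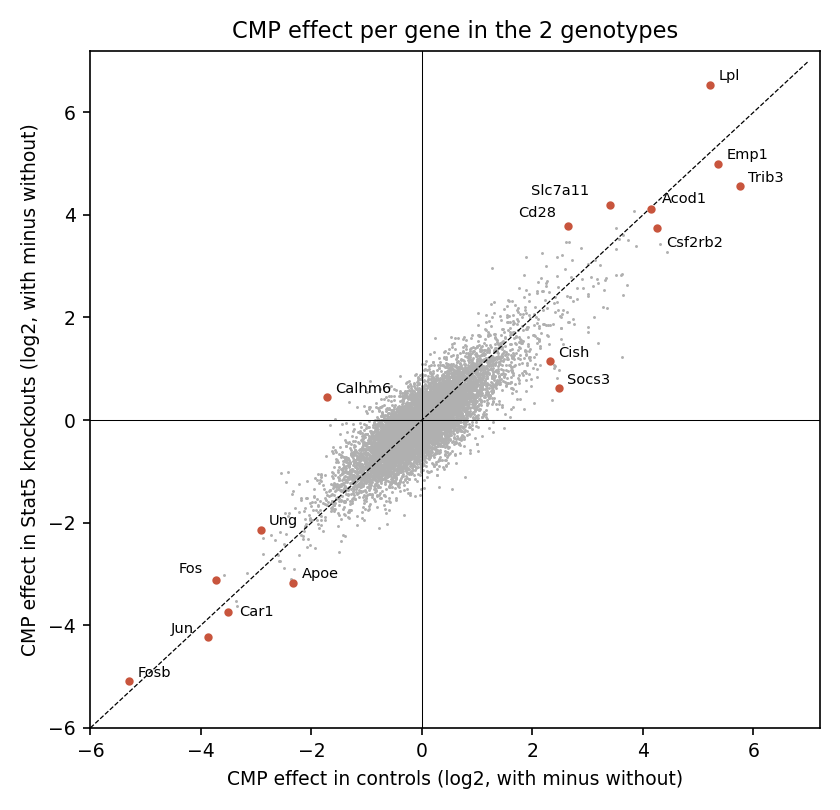
Fitted log2 CMP effect of each tested gene in the Stat5 knockouts (vertical axis) against that in the controls (horizontal axis), with 1 point per gene, a dashed line of equal effects and named genes in red. Lpl lies at 5.22 and 6.54, Fosb at -5.30 and -5.09, Cish at 2.31 and 1.16, and Calhm6 at -1.72 and 0.45.

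**Figure D4:**
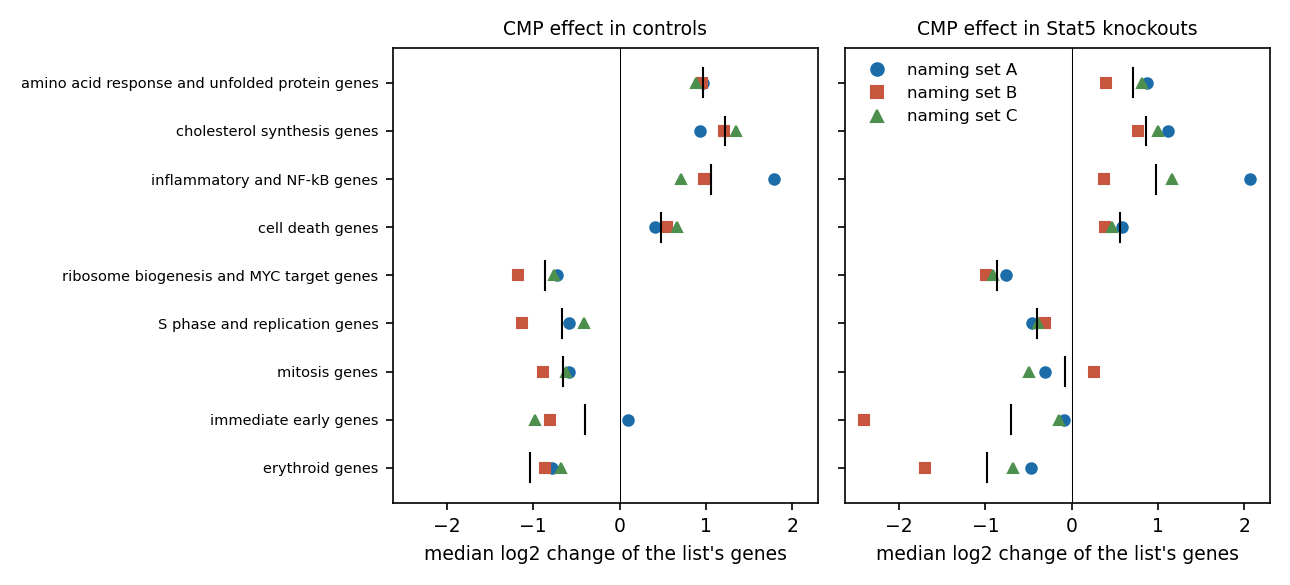
Median log2 CMP effect of the members of 9 gene lists in controls (left) and in Stat5 knockouts (right), with 1 point per naming set and a bar at the median of the fitted effects. The immediate early list in the knockouts spans -2.40 in set B to -0.09 in set A.

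The knockout effect without CMP asked which genes differ between the genotypes in arrays labelled without CMP. Only Stat5a and Stat5b passed in limma, both lower in the knockouts as given above. Of the other genes, Stat3, a related transcription factor, stood at 1.35 ± 0.29 (SE, n = 3; adjusted p = 1), with values of 1.76, 1.60 and 0.70 in sets A, B and C. As lists, megakaryocyte and erythroid genes stood lower in the knockouts and monocyte genes higher by camera with the preset correlation, with no called member. With an estimated correlation these lists had an adjusted p = 0.161, 0.465 and 0.342.

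At an unadjusted p under 0.05 there were 250 genes, with 529 expected by chance. The fit uses 1 estimate of the spread for all 4 groups, so that a count below the expected one is no evidence that the genotypes are alike. The genes with the smallest p beside Stat3 were Ager (1.47), Tmem243 (0.95), Trps1 (0.76) and Pmaip1 (0.87) above 0, and Klf9 (-0.89), Ces2g (-1.16) and Pisd-ps3 (-0.47) below 0, each in 3 of 3 naming sets and each with an adjusted p of 1. These genes were chosen for a small p in a fit over the same sets, so that this agreement is no separate support. Ager and Tmem243 had a mean below the level filter in the controls, and were at 0.82 and 0.59 with a constant of 100 and at 2.80 and 1.34 with 1. Megakaryocyte and platelet genes had a median of -0.48, with medians of -0.49, -0.56 and -0.39 in the sets (camera adjusted p = 3.57e-06, and adjusted p = 0.161 with an estimated correlation). Vwf, the von Willebrand factor, was at -0.75 ± 0.21 and the platelet glycoprotein gene Gp5 at -0.59 ± 0.22. All 17 erythroid genes were below 0, with a median of -0.46 (adjusted p = 1.75e-05, and adjusted p = 0.465 with an estimated correlation), among them Rhd (-0.63) and Rhag (-0.58). Monocyte and macrophage genes had a median of 0.69 (adjusted p = 2.17e-05, and adjusted p = 0.342 with an estimated correlation), with Cd68 at 0.90 ± 0.35 and Mpeg1 at 0.87 ± 0.34. All 13 primary granule genes were above 0, with a median of 0.33 (adjusted p = 0.000284, and adjusted p = 0.419 with an estimated correlation). In set C the monocyte median was -0.10 and the primary granule median -0.07, opposite to sets A and B. The lists of B cell genes (5 members, 0.43), cytokine receptors (0.23), dendritic cell and MHC class II genes (0.22) and amino acid response genes (0.13) also passed upward, with adjusted p of 0.00437, 0.0228, 0.0136 and 0.0187. Endothelial and stromal genes passed downward (-0.45; adjusted p = 0.0158). For these 5 lists, in this order, the adjusted p was 0.429, 0.332, 0.465, 0.36 and 0.565 with an estimated correlation. Without the array of conflicting labels the B cell, cytokine receptor, amino acid response and endothelial lists did not pass (adjusted p = 0.443, 0.11, 0.183 and 0.0547), while the immediate early list (0.338 with all arrays) passed downward (6.37e-07), all with the preset correlation. With an estimated correlation, over all arrays, no list passed camera in this contrast, the immediate early list included (smallest adjusted p = 0.161). Without set A the primary granule, cytokine receptor, dendritic cell and amino acid response lists did not pass (0.121, 0.213, 0.091 and 0.1), without set B the B cell, cytokine receptor and endothelial lists (0.0742, 0.142 and 0.0821), and without set C the endothelial list (0.06). Adjusted over the list alone, these 9 lists had no member called, and the list of JAK-STAT parts, which did not pass (adjusted p = 0.524), had 1, Stat3. With a stricter level filter Stat5a and Stat5b were not tested and 0 genes were called in limma (160 at an unadjusted p under 0.05). With the array of conflicting labels counted as a control 0 genes were called (131 at an unadjusted p under 0.05).

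Among the sex-linked genes, Xist differed between the genotypes within set B. It is transcribed from the inactive X chromosome and gave 9766 and 25187 in the set B knockouts without and with CMP, against 233 and 346 in the set B controls. In set A all arrays lay at 97.7 to 202, and in set C all lay at 8245 to 12509. The Y-linked gene Eif2s3y gave 745 to 2484 in the 12 arrays. The Y-linked genes Kdm5d and Uty were at 588 to 674 and 334 to 467 in set A, at 120 to 204 and 159 to 208 in set C, and at 196 to 349 and 48.6 to 277 in set B. In the set B knockout without CMP Uty, at 48.6, was below the array median of 80.1. Within set B the genotype therefore cannot be told apart from the difference in Xist, which the naming set block does not remove. Both knockout contrasts and the interaction include these arrays.

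With CMP, the knockouts again differed from the controls in Stat5a and Stat5b alone in limma. Stat5a was at -3.76 ± 0.29 and Stat5b at -4.37 ± 0.33 (SE, n = 3; adjusted p = 0.000122 for each), or -2.90 and -3.35 with a constant of 100 and -4.54 and -5.61 with a constant of 1. Cish, a feedback inhibitor of cytokine signalling and a Stat5 target gene, was at -1.67 ± 0.24 (limma adjusted p = 0.0521). Enah, an actin regulator, was at -2.70 ± 0.40 (limma adjusted p = 0.0666). Both were below 0 in 3 of 3 naming sets, but they were chosen for a small p, so that this is no separate support. As lists, mitosis and S phase genes stood higher in the knockouts, and Stat5 target, erythroid and megakaryocyte genes lower, by camera with the preset correlation and without a called member. With an estimated correlation these lists had an adjusted p = 0.282, 0.419, 0.36, 0.514 and 0.262.

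At an unadjusted p under 0.05 there were 1038 genes, with 529 expected by chance. There were 459 without naming set B, 283 without its control with CMP and 312 without its knockout with CMP. Hpse, a heparanase (1.82 ± 0.30, adjusted p = 0.116), Calhm6 (2.40 ± 0.46), Cd28 (1.52), Pmaip1 (1.27) and Evl (1.54) were the genes above 0 with the smallest p. Gimap8 was at -1.63 ± 0.32 (adjusted p = 0.412). Cish was called in 6 other settings and Enah in 5, and array weights, added after the data were seen, raised the count to 13. That count held Stat5a, Stat5b, Cish, Enah, Hpse, Calhm6, Cd28, Stat3, Ifitm1, Eps8, Lgmn, Malt1 and Cd52, the last 6 named after their values were seen.

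Of the 31 mitosis genes 29 were above 0, with a median of 0.55 and set medians of 0.32, 1.02 and 0.22 in A, B and C. Cdk1 was at 0.72 ± 0.21, Prc1 at 0.65 ± 0.20 and Kif20a at 0.88 ± 0.29. The list had a camera adjusted p = 1.1e-12, and adjusted p = 0.282 with an estimated correlation. Of the 30 S phase genes 26 were above 0, with a median of 0.34 and set medians of 0.10, 0.84 and 0.12. Dut was at 0.72 ± 0.22 and Gins1 at 0.95 ± 0.29. Their adjusted p was 3.51e-07, and adjusted p = 0.419 with an estimated correlation. Stat5 target genes had a median of -0.41, with set medians of -0.10, -0.64 and -0.33. Beside Cish, Socs3 was at -1.97 ± 0.48, Pim1 at -0.80 ± 0.32 and Bcl2l1 at -0.64 ± 0.21. The list had an adjusted p = 0.0139, and adjusted p = 0.36 with an estimated correlation and 0.173 without set C, with 2 members lower adjusted over the list alone.

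Erythroid genes had a median of -0.63 (adjusted p = 9.54e-05, and adjusted p = 0.514 with an estimated correlation), with Aqp1 at -1.43 and Hemgn at -0.90. Megakaryocyte genes had a median of -0.41, with 6 members lower adjusted over the list alone, an adjusted p = 0.000315, and adjusted p = 0.262 with an estimated correlation. Gp1bb was at -1.32 ± 0.36 and Vwf at -0.84 ± 0.21, and this list also passed fry (adjusted p = 0.0326). Secondary granule and neutrophil genes had set medians of 0.16, -2.19 and 0.03, with Ltf at -1.82 and Cd177 at -1.74. Their adjusted p was 0.00296, and adjusted p = 0.833 with an estimated correlation, and without set B the direction turned (adjusted p = 0.142). Monocyte genes had a median of 0.43 with 5 members higher adjusted over the list alone, and F13a1 was at 1.43 and Ctss at 0.83 (adjusted p = 0.0246, adjusted p = 0.637 with an estimated correlation and 0.319 without set A). Primary granule genes, with Ctsg at 0.90, had a median of 0.30 and set medians of 0.85, -0.07 and -0.12 (adjusted p = 0.016, adjusted p = 0.628 with an estimated correlation and 0.777 without set A). Stem and progenitor genes (-0.33; adjusted p = 0.0425, and adjusted p = 0.685 with an estimated correlation) and cholesterol synthesis genes (-0.24; adjusted p = 0.0284, and adjusted p = 0.465 with an estimated correlation) had medians below 0 and did not pass without set B (adjusted p = 0.17 and 0.0517), nor did the cholesterol list without set A (0.0739) or set C (0.0635). Centring the arrays on their medians moved the median of all genes from -0.04 to 0.15. The list medians were then 0.53 for S phase, 0.49 for primary granule, -0.22 for Stat5 target, -0.22 for megakaryocyte, -0.13 for stem and progenitor and -0.04 for cholesterol synthesis genes. With the stricter level filter 0 genes were called in limma (746 at an unadjusted p under 0.05), in a fit of these 6 arrays alone 0 (480), and with the array of conflicting labels as a control 0 (1000). In set B the knockout with CMP also had the highest beta-actin ratio, 54.8, against 33.4 in the control.

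**Figure D5:**
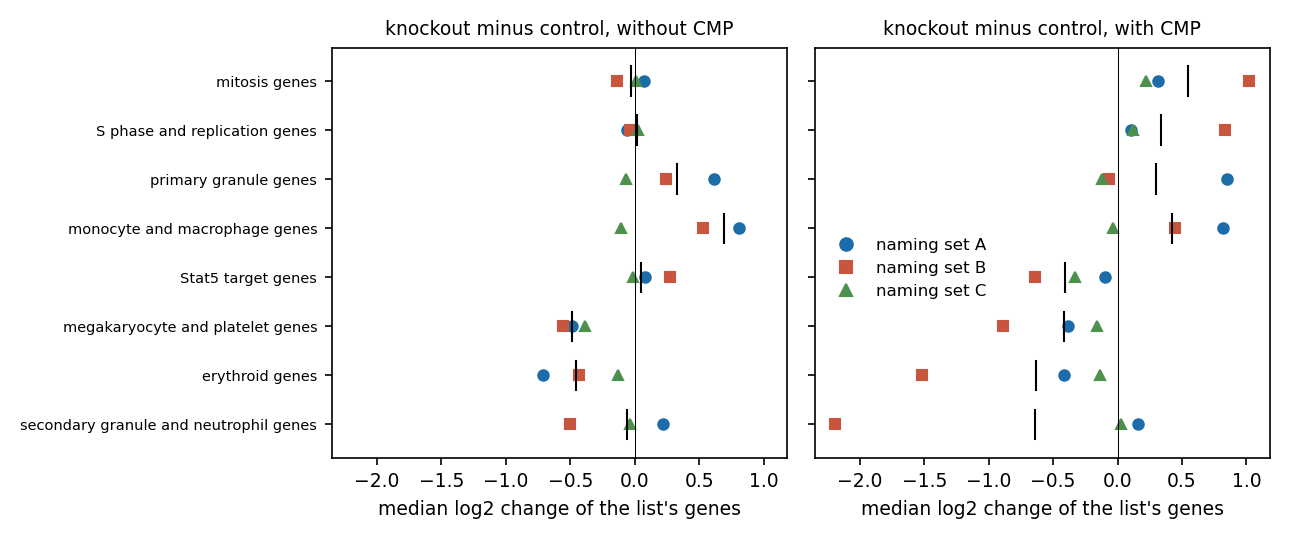
Median log2 difference between knockouts and controls of the members of 8 gene lists, without CMP (left) and with CMP (right), with 1 point per naming set and a bar at the median of the fitted differences. With CMP the mitosis medians are 0.32, 1.02 and 0.22 in sets A, B and C, and the secondary granule median is -2.19 in set B.

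The interaction asked whether the CMP effect differs between the genotypes. As lists, Stat5 target genes had a lower CMP effect in the knockouts than in the controls, and S phase and mitosis genes a higher one, by camera with the preset correlation. With an estimated correlation their adjusted p was 0.196, 0.445 and 0.289. No gene passed in limma (0 of 10583, smallest adjusted p = 0.954). At an unadjusted p under 0.05 there were 223, with 529 expected by chance, which is no evidence that the CMP effects are alike. Cish was at -1.15 ± 0.34 and Enah at -2.40 ± 0.57, each below 0 in 3 of 3 naming sets. Both were chosen for a small p, so that this agreement is no separate support. Enah had group means below the level filter, and its interaction was -2.08 and -2.79 with a constant of 100 and 1.

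The Stat5 target list had a median of -0.37 and an adjusted p = 0.000233, and adjusted p = 0.196 with an estimated correlation. In the controls 5 of its 19 members rose with CMP and 3 fell, and in the knockouts 4 rose and 3 fell, the same counts as adjusted over the list alone. Cdkn1a, a cell cycle inhibitor, rose by 3.28 ± 0.33 in the controls and by 2.20 ± 0.33 in the knockouts, and Cish by 2.31 ± 0.24 and 1.16 ± 0.24. Bcl2, a survival gene, fell by 1.72 and 1.66. The interaction of Socs3 was -1.85 ± 0.68. S phase genes had a median of 0.36 (adjusted p = 1.55e-06, and adjusted p = 0.445 with an estimated correlation), with set medians of 0.13, 0.96 and 0.11, Gins1 at 0.95 and Dut at 0.69. Mitosis genes had a median of 0.58 (adjusted p = 2.87e-12, and adjusted p = 0.289 with an estimated correlation), with set medians of 0.28, 1.20 and 0.15, Nuf2 at 0.94 and Prc1 at 0.75. Secondary granule genes had a median of -0.52 (adjusted p = 0.00383, and adjusted p = 0.837 with an estimated correlation), with Cxcr2 at -1.07, and an adjusted p = 0.932 without set B. The other genes with the smallest p were Epha2 (1.70), Calhm6 (2.17), Hirip3 (1.37), Cdkn2c (0.91) and Ccdc122 (1.11) above 0, and Prmt1 (-1.40), Batf3 (-1.97) and Thy1 (-1.30) below 0, each with an adjusted p of 0.954. Epha2 and Batf3, also with group means below the level filter, were at 1.04 and 2.55 and at -1.46 and -2.36 with a constant of 100 and 1. With the arrays centred on their medians the median of all genes moved from -0.02 to 0.11, and that of the Stat5 target list to -0.24.

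Over all 125 list tests, 41 passed with the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.0959). In fry 14 passed, and 11 passed in both fry and camera with the preset correlation. By comparison, fry passed 8 lists for the CMP effect in controls, 5 in knockouts, 0 for the knockout effect without CMP, 1 with CMP and 0 for the interaction.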

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

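The tests of RNA quality, with both covariates, of the wider spread of naming set B, with array weights, and of the interaction lists without set B were chosen only after the results were seen.

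The CMP effect differed between the genotypes in 4 gene lists by camera on the interaction, with the preset correlation. Mitosis genes (median 0.58, adjusted p = 2.87e-12) and S phase and replication genes (0.36, adjusted p = 1.55e-06) had a higher CMP effect in the knockouts. Stat5 target genes (-0.37, adjusted p = 0.000233) and secondary granule and neutrophil genes (-0.52, adjusted p = 0.00383) had a lower one. With an estimated correlation the adjusted p of these lists was 0.289, 0.445, 0.196 and 0.837, and without set B, with the preset correlation, it was 6.38e-07, 0.0237, 2.84e-05 and 0.932. For Calhm6 and Epha2 the 3 control differences with CMP were below 0 and the 3 knockout differences above 0, one per naming set, with interactions of 2.168 and 1.701 on the log2 scale that did not pass in limma (adjusted p = 0.954 for each). The size for Epha2 depends on the added constant (1.04 with 100 and 2.55 with 1). These came from 49 named genes looked at, and 80 of all 10583 genes (0.756%) had opposite signs in this way, for which the share without a difference is not known, as the arrays of a naming set are not independent.

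The first pattern is the many genes called for the CMP effect in both genotypes. At least 83.32% of the called genes stayed called in the same direction after quantile normalization or median centring, which argues against the authors' scaling as the whole cause. If RNA quality were the whole cause, the changes would be smaller in set C than in set A, where the ratios changed more (set C over set A 0.440 and 0.150 for beta-actin and 0.362 and 0.257 for Gapdh, in controls and knockouts). For the 1000 genes that moved most in set B, chosen without sets A and C, the mean change in set C was instead 1.154 and 1.215 times that in set A. The called genes gave 1.096 and 1.106, but they were chosen on all sets together, which favours like changes, so that these 2 values decide nothing. With the beta-actin ratio as a covariate the counts went from 2344 to 1519 and from 1985 to 650, with 1261 and 566 of the first calls kept, and with the Gapdh ratio to 2520 and 1192, with 1868 and 899 kept, and since the beta-actin ratio was higher with CMP in 6 of 6 pairs, the covariate shares variation with CMP. A part played by RNA quality therefore stays open, beside the hypothesis of a biological difference between cells labelled with and without CMP, whatever CMP names.

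The second pattern is that Stat5a and Stat5b were the only genes called between the genotypes. Too few arrays may hide further differences, since 46% of simulated 2-fold changes were recovered without CMP and 50% with CMP. Of simulated 4-fold changes, 98% were recovered in each. The simulation changed 100 genes 2-fold and 100 genes 4-fold at once, which makes the adjusted threshold less strict than with 2 called genes. These shares are therefore too high where few genes differ. Enah, more than 4-fold lower in the knockouts with CMP, was not called. The spread of set B may also hide some, since array weights gave 13 genes with CMP, but they gave 2 without CMP, and leaving set B out gave 2 in each. From these arrays, neither can be told apart from a small number of genes that differ by genotype. The recovery of 2-fold changes was below the lower bound set, 50%, without CMP, but at it with CMP. The 2 ways of lowering the weight of set B gave different counts.

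The third pattern is the higher S phase and mitosis lists in the knockouts with CMP. Without set B the higher of their 2 camera adjusted p was 0.00243, with medians above 0 in sets A and C, which argues against set B alone carrying the call, although its medians of 0.84 and 1.02 lie above the 0.10 to 0.32 of the other sets. The beta-actin ratio of knockout over control was below 0 on the log2 scale in sets A and C (-0.17 and -0.39) and above 0 in set B (0.71), while both list medians were above 0 in 3 of 3 sets. This argues against RNA quality setting the direction in sets A and C. It leaves the size open, since set B, with the only ratio above 0, also had the largest medians. The set B knockouts also differed from the set B controls in Xist, and the size of the set B medians cannot be told apart from that difference. The calls were lost with an estimated correlation (adjusted p = 0.419 and 0.282). A difference in dividing cells between the genotypes in arrays labelled with CMP is a hypothesis that stays open, untested beyond these lists.

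Each contrast of 2 groups allows 10 splits of its 6 arrays, too few for a share under 0.05. For the CMP effect 1 split, the real one, reached its own count, 2344 in the controls and 1985 in the knockouts, and the highest other gave 0 in each. For the knockout effect without CMP 1 split, the real one, reached 2 genes, and the highest other gave 0. With CMP 3 splits reached 2 genes, the real one and others with 4 and 3, and both of these put the arrays of set A on one side and those of set C on the other, in a fit that already holds the naming set as a block. For the interaction the real count in limma was 0 (223 at an unadjusted p under 0.05), which 100 of 100 regroupings of the 12 arrays reach by construction, so that they decide nothing about chance. The highest other gave 1194 and the next 13. A regrouping that calls so many genes points to a structure of the samples, which was not tested. It had 1 of 6 arrays on the plus side with CMP, but 4 other regroupings of that composition gave 0, so that the composition by CMP alone does not account for it.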

How the results depend on the processing

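Array weights, both covariates and the list tests without a naming set, with array weights or with the beta-actin covariate were tests chosen only after the data were seen. Unless a reason is given, the cause was not tested.

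Without the naming set block the CMP effect gave 470 genes in the controls and 298 in the knockouts. Without set A it gave 1055 and 679, without set C 571 and 356, and without set B 3074 and 2648. Array weights gave 4151 and 4008, and 13 for the knockout effect with CMP. The beta-actin covariate gave 1519 and 650. The Gapdh covariate gave 2520 and 1192, and 4 for the knockout effect with CMP. In fits of the compared groups alone the CMP effect gave 2592 in the controls and 662 in the knockouts, and the knockout effect with CMP 0 in limma (480 at an unadjusted p under 0.05). The array with conflicting labels, left out or counted as a control, gave 1000 and 972 for the CMP effect in the knockouts. As a control, this array, with the low Stat5a and Stat5b signals of a knockout, widens the spread of these genes among the controls. It then gave 0 for the knockout effects without and with CMP (131 and 1000 at an unadjusted p under 0.05). The stricter level filter also gave 0 for both (160 and 746), since it removed Stat5a and Stat5b. A pseudocount of 100 and the naming set as a random block each gave 4 for the knockout effect with CMP. The interaction gave 0 genes in limma in the 30 other settings run (36 to 569 at an unadjusted p under 0.05).

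Leaving out 1 array in turn gave 1291 to 3450 genes for the CMP effect in the controls, 937 to 2368 in the knockouts, 2 for the knockout effect without CMP and 2 to 4 with CMP, the 4 without the control with CMP of set A. In the controls the count was 1294 and 1291 without the control without CMP of set B and C, and 1494 and 1505 without the control with CMP of set B and C. In the knockouts it was 1298, 1000 and 937 without the knockout without CMP of set A, B and C. Without a level filter, where genes of low signal entered and more genes were adjusted over, 1966 and 1544 genes were called for the CMP effect.

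With an estimated correlation 0 of the 41 list shifts passed. Over 10 settings, 327 of their 410 values kept direction and call, 79 did not pass and 4 reversed. Of the 84 list tests that did not pass, 23 passed in at least 1 other setting with the preset correlation. Among them, interferon-stimulated genes passed camera upward for the knockout effect with CMP without set B (adjusted p = 0.00127) and with array weights (3.31e-10). Their interaction passed upward in these settings (0.00664 and 4.21e-05) but downward without set A (0.0184). Without set B the interaction also passed downward for dendritic cell genes (0.0114) and upward for immediate early genes (0.0161). These lists were picked after their values were seen. The 4 values that reversed were those of secondary granule genes. They were for the CMP effect in the knockouts with the beta-actin covariate (camera adjusted p = 0.999) and for the interaction with array weights (0.747). The others were for the knockout effect with CMP, without set B (0.142) and with array weights (0.418).

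Changes of Stat5a and Stat5b that were not called also reversed. With the array of conflicting labels as a control, the CMP effect in the controls was 0.58 for Stat5a and 0.546 for Stat5b, and that of Stat5b in the knockouts 0.194. This array had the signals of a knockout, 50.1 for Stat5a and 32.3 for Stat5b. Controls without CMP had 1081 to 1316 and 1227 to 2177. Counting it as a control lowers their mean, so that the reversals in the controls follow from this grouping. Leaving out 1 array gave -0.573 to 0.017 for Stat5a in the controls, and -0.473 to 0.043 for Stat5a and -0.449 to 0.139 for Stat5b in the knockouts. The interaction of Stat5a was -0.001 with quantile normalization, -0.099 with a pseudocount of 1, -0.154 without the array of conflicting labels, -0.753 with it as a control, -0.014 without set A and -0.292 to 0.362 with 1 array left out. That of Stat5b was -0.076 with a pseudocount of 1, -0.352 with the relabelled array and -0.138 to 0.551 with 1 array left out.

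Of 6279 values of 204 called changes of named genes, 5612 stayed called in the same direction, 667 were no longer called and 0 reversed. Named genes were chosen for large changes of the same sign in all naming sets or for small p, which made reversals unlikely from the start. Among all genes called for the CMP effect, up to 23 in the controls and 13 in the knockouts reversed sign in a single setting. The Pearson correlation of the CMP effects between the genotypes ranged from 0.706 without set C to 0.922 without set B over 30 settings.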

Other observations

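The list tests without a naming set and with array weights or the beta-actin covariate were tests chosen only after the results were seen, and Afp was named after its values were seen.

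Several further gene groups held members that moved with CMP, while their lists did not pass camera. Of 26 glycolysis and hypoxia genes, 3 rose and 8 fell in the controls and 3 rose and 5 fell in the knockouts (list adjusted p = 0.452 and 0.398). The glycolytic enzymes Tpi1 (-1.51 ± 0.18 and -1.16 ± 0.18 in controls and knockouts, SE, n = 3) and Pfkl (-1.39 and -1.85) fell, and Vegfa, a growth factor of vessels, rose by 1.65 ± 0.26 in the knockouts (1.17 and 2.08 with an added constant of 100 and 1, as its mean without CMP was below the level filter). Of 12 ERK feedback genes, 4 rose and 2 fell in the controls and 2 rose and 3 fell in the knockouts (adjusted p = 0.811 and 0.947). The ERK phosphatase Dusp6 (-2.73 ± 0.31 and -2.24 ± 0.31) fell and the inhibitor Spred1 (1.48 and 1.34) rose. Of 32 interferon-stimulated genes, 2 rose and 3 fell in the controls and 1 rose and 2 fell in the knockouts (adjusted p = 0.703 and 0.747). The immunoproteasome genes Psmb8 (-1.42 and -1.37) and Psmb9 (-1.49 and -1.37) fell and Rsad2 rose (2.62 ± 0.59 and 2.42 ± 0.59). Of 22 cytokine receptors, 5 rose and 1 fell in the controls and 5 rose in the knockouts (camera adjusted p = 0.0544 and 0.0804), a list that passed fry in each (0.0168 and 0.0278), with Tgfbr1, a TGF-beta receptor, at 1.53 and 1.92. Of 18 JAK-STAT parts, 2 rose in the controls, and 2 rose and 1 fell in the knockouts (adjusted p = 0.233 and 0.148), with the adaptor Sh2b3 at 1.82 ± 0.21 and 1.84 ± 0.21. Adjusted over the list alone, these counts up and down were 5 and 8 and then 3 and 6 for glycolysis, 5 and 4 and then 2 and 3 for ERK feedback, 1 and 3 and then 1 and 2 for interferon, 6 and 1 and then 5 and 1 for cytokine receptors, and unchanged for JAK-STAT parts.

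Cell type genes went both ways with CMP. Of 17 monocyte and macrophage genes, 4 rose and 2 fell in the controls and 5 rose and 3 fell in the knockouts (adjusted p = 0.314 and 0.378), with the lectin Lgals3 (3.22 ± 0.25 and 3.03 ± 0.25) and Cd14 (2.03 and 1.85) up. Of 28 stem and progenitor genes, 3 rose and 3 fell in the controls and 1 rose and 3 fell in the knockouts (adjusted p = 0.974 and 0.605), with Angpt1 (-2.02 ± 0.24 and -1.68 ± 0.24) and Cd34 (-1.07 and -1.04) down. Of 18 megakaryocyte and platelet genes, 2 rose and 2 fell and then 1 rose and 4 fell (0.416 and 0.276), with Gp5 at -1.74 and -1.55. Of 10 T and NK cell genes, 2 rose and 1 fell and then 2 rose and 2 fell (0.181 and 0.362), with Cd28 at 2.65 (1.99 and 3.24 in the controls with a constant of 100 and 1) and 3.79 and Nkg7 at -2.02 and -1.96. Of 12 dendritic cell and MHC class II genes, 2 rose and 1 fell and then 2 rose and 2 fell (0.396 and 0.993), with H2-DMa at -1.32 and -1.30. Of 11 mast cell and basophil genes, 1 rose and 1 fell and then 1 rose and 2 fell (0.832 and 0.579), with the protease Cpa3 at -2.02 and -1.92. Of 13 primary granule genes 3 fell in each genotype (0.205 and 0.188), among them Prtn3 (-0.61 and -0.60), and of 5 B cell genes 1 fell in each, Jchain (-2.60 and -2.75, or -1.90 and -2.08 with a constant of 100 and -3.29 and -3.52 with 1; list 0.243 and 0.139). Of 24 secondary granule genes in the controls 1 rose, Ncf1 (1.11 ± 0.21; list 0.762), and of 8 endothelial and stromal genes 0 were called in limma in each (0.871 and 0.936).

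Adjusted over the list alone, the counts up and down in the controls and then in the knockouts were 5 and 2 and then 6 and 3 for monocyte genes, 3 and 3 and then 1 and 7 for megakaryocyte genes, 3 and 1 and then 2 and 2 for T and NK cell genes, and 4 and 1 and then 3 and 2 for dendritic cell genes. They were 2 and 4 in each for mast cell genes, 0 and 3 and then 2 and 5 for primary granule genes, 0 and 1 and then 0 and 3 for B cell genes, and the same as over all genes for the stem cell and endothelial lists in both genotypes and for the secondary granule list in the controls. The Stat5 target list did not pass camera for the CMP effect (adjusted p = 0.0762 and 0.871). In the controls it passed fry (adjusted p = 0.0492), and passed camera upward with quantile normalization (0.0491), without set B (0.0472) and with array weights (0.0269), but had an adjusted p = 0.465 with an estimated correlation. Among the settings in which other lists passed, cytokine receptors passed upward without set B (0.0307 and 0.0371) and with array weights (0.0248 and 0.0307), and JAK-STAT parts did so in the knockouts (0.02 and 0.0248). B cell genes passed downward without set A (0.0408 and 0.0287). Interferon-stimulated genes in the knockouts passed downward without set A (0.0189) and upward without set C (0.039), as in the controls without set C (0.00938). These calls used the preset correlation. With an estimated correlation, over all arrays, the adjusted p was 0.394 and 0.419 for cytokine receptors, 0.833 for JAK-STAT parts in the knockouts, 0.833 and 0.702 for B cell genes and 0.996 in each for interferon-stimulated genes. Some of these tests had a sign that the list's median or mean did not share. In the knockouts the upward tests were those of monocyte genes (median -0.08, mean 0.14), dendritic cell genes (-0.15 and -0.03), ERK feedback genes (0.13 and -0.08) and Stat5 target genes (median -0.01). In the controls the upward test of stem cell genes had a median of -0.05 and a mean of 0.04.

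Afp, the only tested hepatocyte gene, was at 0.59 ± 0.43 with CMP in the controls (adjusted p = 0.353) and rose by 1.51 ± 0.43 in the knockouts (adjusted p = 0.0307), by 0.38, 2.94 and 1.21 in sets A, B and C, with an interaction of 0.92 ± 0.61 (adjusted p = 0.954). The log2 change of Afp, CMP effect in Stat5 knockouts, was not called without the knockout with CMP of set B (adjusted p = 0.0549), or without the knockout without CMP of set B (0.136) or of set C (0.0948). The only tested eosinophil gene was not called in any of the 5 contrasts. The signal of the spiked-in control BioB was 2090 to 5661 in the arrays of set B and 303 to 720 in those of sets A and C. That of the spiked-in control Lys was 34887 to 76390 in set B and 491 to 2359 in sets A and C. The cause was not tested.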
